A study of Homo sapiens with 6 samples.

How the data were processed

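RNA from 6 cell line samples was measured on one-colour Agilent arrays with Cy3 label: 2 parental and 2 AZD9291-resistant H1975 samples, and 1 parental and 1 resistant HCC827 sample. Groups and replicate numbers were taken from the source names in the labels. Total RNA was extracted, amplified and labelled, per the labels' protocols, which describe no step that removes linear RNA, so signal from linear transcripts on circRNA probes is not excluded.

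The values used were those of the deposited value table, one column per sample. They were read as log2 signal, normalized between arrays by the authors: all 6 columns share the lowest value (0.672) and the highest (18.06), and their medians lie between 4.15 and 4.16, as quantile normalization gives. The scale was inferred from the values, since 18.06 fits a scanner's range only as log2. Agilent Feature Extraction 11.0 and limma are named in the submitters' processing notes, without their roles; the background correction and any filter are not given in the sources used here. Values are not centred on genes and have no ratio direction. Such a normalization forces the same distribution on each array, so a change in the total signal of an array would not be seen, and one of all circRNAs together only relative to the LNCV6 probes. A second deposited table has 6 value columns whose names match no label, and it was not used. The plan had named that table as the main source; the value table took its place, which also removed the planned comparison of the 2 sources, and the planned pseudocounts were not needed for log2 values.

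Probes fell into 4 classes by their identifiers: 88371 circRNAs, 87276 LNCV6 probes, 379 further probes whose identifier adds a suffix to a circRNA's (called companion probes here, with the meaning of the suffix not stated in the files) and 56 control spots. Companion and control probes were left out of the tests. None of the 176082 identifiers matched the RefSeq gene table supplied (0 matches), and no gene names come with the files. The gene list tests (28 lists of 614 symbols fixed beforehand), the comparison of circRNAs with host transcripts and the limit of 1 circRNA per host gene could therefore not be run. Names such as circHIPK3 are given for circRNAs chosen by their circBase number, and no genome position is given.

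The lowest 25% of features by mean signal over the 6 arrays (log2 under 1.64) were left out, which kept 131735, of which 80365 were circRNAs and 51370 LNCV6 probes. A probe was called near background when its log2 signal was under the higher of the dark corner and negative control means plus 1, giving 2.09 to 2.28 per array. This level was chosen after seeing the data, as the files hold no detection calls. Where every array of a group was near background, the fold is given as "at least", against the group's mean of that level.

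Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on mean signal), two-sided, with Benjamini-Hochberg adjustment over all features kept and a threshold of 0.05. Resistant and parental H1975 cells were compared on the 4 H1975 arrays. The shared change and the difference between lines came from 1 fit of all 6 arrays with resistance and cell line as terms, and the difference of response from the 4 group means. HCC827 has 1 array per group, so its changes are given without a test. Figures were drawn with matplotlib 3.10.9.

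Whether replicate numbers pair the samples was checked before the fits were compared. Over the features kept, deviations from the mean of the 3 parental or the 3 resistant arrays correlated within the 3 pairs at 0.494, 0.374 and 0.464, and at 0.439 within H1975 alone. All 3 exceed 0.1, the limit set beforehand, but the HCC827 arrays deviate together through their cell line whatever their number. Only the value within H1975, from 2 pairs, bears on the numbers. On that value the numbers were taken to pair the samples, and values within pairs stand beside the results they change. In the cell line comparison the replicate number was the block, and since HCC827 has number 1 only, that fit takes its line difference from the replicate 1 arrays alone.

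CircRNAs to be named were fixed by rule before the data were examined. For H1975 they were the 10 in each direction, for both lines the 5 in each direction, with called features first and remaining places going to the smallest unadjusted p among those changed at least 2-fold. No resistance comparison had called features, so every circRNA named for H1975 or both lines came in by the second part. For HCC827 the 5 largest differences in each direction among circRNAs at or above the median signal were taken. Only 2 LNCV6 probes in each direction are named, as their targets are unknown, where the plan had 5. The called circRNAs of the cell line comparison and a list of 16 known circRNAs complete the set.

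The H1975 and both-line fits were tested on simulated arrays of 131735 features with 200 changed, 50 at each log2 change of 1, 2, 3 and 5. With the spread of these arrays, the H1975 fit recovered 0, 0, 1 and 32 of each 50, and the both-line fit 0, 5, 23 and 38. Beside these recoveries the former made 8 false calls and the latter 13. Noise was simulated as independent between arrays, whereas the real arrays with one number deviated together. The recoveries may therefore not hold for the real data. With a spread of 0.2 log2 units, the H1975 fit recovered 39, 50, 50 and 50, with 12 false calls. Alternatives covered the filter, the normalization, the variance prior, the threshold, the replicate block, each array left out in turn and, chosen after seeing the data, each pair left out, a lowess correction and values raised to the background level.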

Results

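Circular RNAs (circRNAs, RNA loops closed by splicing a downstream exon end back to an upstream one) were measured in 2 lung cancer cell lines and in derivatives selected to grow in AZD9291 (osimertinib, an inhibitor of mutant EGFR). H1975 and HCC827 are lung adenocarcinoma lines that depend on mutant EGFR. The series was made to profile circRNAs in resistant cells. Each one-colour array held 176082 features, of which 88371 were circRNA probes named by their circBase numbers and 87276 carried identifiers beginning with LNCV6, whose targets are not named in the files. There were 2 parental and 2 resistant H1975 arrays, and 1 parental and 1 resistant HCC827 array. Resistant cells were kept in 10 µM AZD9291 and parental cells without drug. An effect of the drug itself therefore cannot be told apart from resistance in any comparison of resistant with parental cells. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. On each array between 83.7% and 87.9% of circRNA probes and between 52.3% and 54.0% of LNCV6 probes lay above the background level, a log2 signal of 2.09 to 2.28 depending on the array.

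The resistant and parental arrays with one replicate number resembled each other more than the replicates of one group did. Across the 131735 features kept (features are not independent replicates), Pearson's r of the log2 signal was 0.942 to 0.972 between the resistant and parental arrays of one line and number, called a pair here. It was 0.902 between the 2 parental H1975 arrays and 0.905 between the 2 resistant ones. The H1975 replicate 2 arrays correlated better with HCC827 (0.932 to 0.946) than with H1975 replicate 1, and the H1975 replicate 1 arrays stood apart from the other 4 on the first principal component, which held 41.3% of the variance. In the parental H1975 cells, 31.6% of features differed at least 2-fold between the replicates. Between resistant and parental cells the share was 21.5% in H1975 pair 1 and 22.8% in H1975 pair 2.

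**Figure D1:**
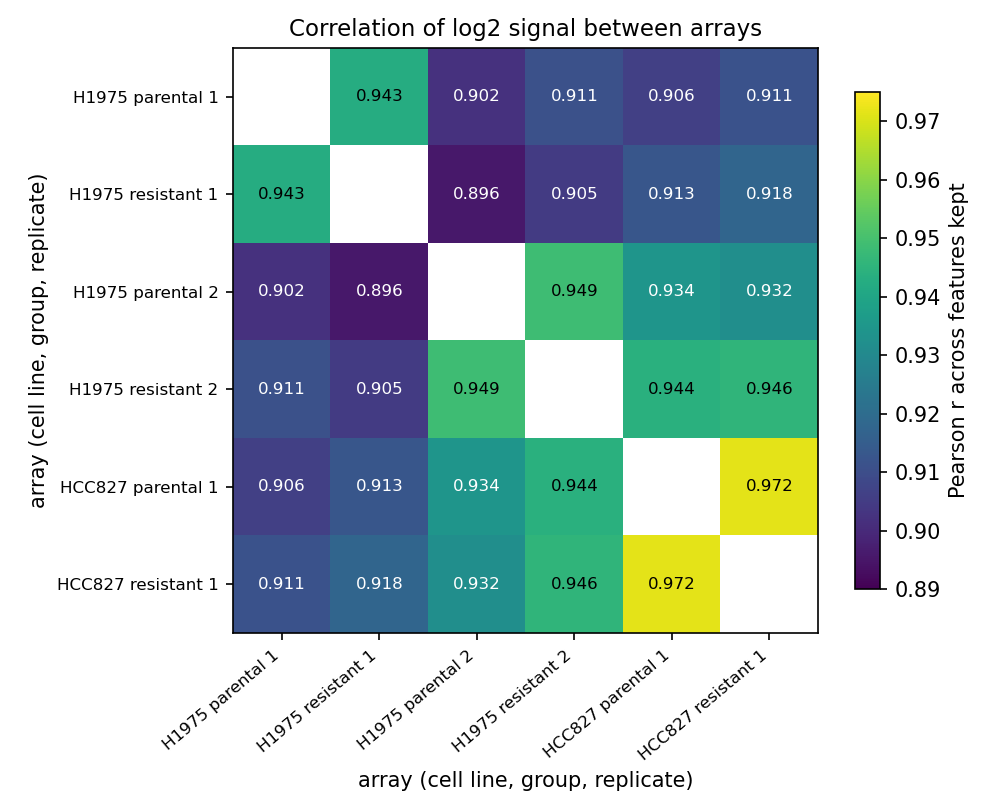
Pearson correlation of log2 signal across the 131735 features kept, for each pair of the 6 arrays (rows and columns are arrays, named by line, group and replicate; colour and printed value give r). The 2 H1975 replicate 1 arrays have their highest r with each other (0.942), and every other r they have is 0.918 or lower.

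Resistant H1975 cells were compared with parental H1975 cells to ask which circRNAs differ with resistance. The circRNA with the smallest p among those higher in resistant cells was hsa_circ_0043610, at a log2 signal of 5.62 ± 0.93 (SD, n = 2) in resistant and 1.08 ± 0.45 in parental cells. The parental signals were near background on both arrays, so resistant cells held at least 10.4-fold more (16.4-fold by replicate 1 and 6.62-fold by replicate 2). Next came hsa_circ_0065833 (4.49 ± 0.36 in resistant cells, at least 4.75-fold more than in parental cells) and hsa_circ_0075641 (5.93 ± 0.57 against 2.78 ± 0.15). Among those lower in resistant cells, hsa_circ_0079560 stood at 1.06 ± 0.38 against 4.90 ± 0.49 in parental cells (at least 6.88-fold less) and hsa_circ_0030789 at 0.90 ± 0.25 against 4.57 ± 0.24 (at least 5.47-fold less). The signal of hsa_circ_0006912 was 3.43 ± 0.22 in resistant and 6.04 ± 0.15 in parental cells, and that of hsa_circ_0083084 was 7.33 ± 0.02 and 9.91 ± 0.73. None of these differences passed the test over all features when group means were compared. All of them passed within pairs, in a test with 1 residual degree of freedom that is described below.

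Several of the named circRNAs carried neighbouring circBase numbers. On the higher side, parental signals were near background on both arrays for hsa_circ_0077059, hsa_circ_0077063 and hsa_circ_0065830, which were at least 21.2-fold, 14.0-fold and 4.61-fold higher by the mean of the resistant arrays. The first pair of these bounds rests mostly on replicate 1, since replicate 2 alone gave 8.35-fold for hsa_circ_0077059 and 5.73-fold for hsa_circ_0077063. The log2 differences were 2.24 (SE 0.44) for hsa_circ_0022128 and 2.18 (SE 0.43) for hsa_circ_0022129. They were 2.90 for hsa_circ_0022131 and 2.91 for hsa_circ_0091478, each with 1 of its 2 parental signals near background. On the lower side, hsa_circ_0083082 had a difference of -2.36 (SE 0.47), hsa_circ_0016236 of -2.14, hsa_circ_0019975 of -2.83 and hsa_circ_0060328, near background on 1 of 2 resistant arrays, of -2.65. The resistant signals of hsa_circ_0064977 and hsa_circ_0067665 were near background on both arrays, at least 4.15-fold and 3.47-fold below the parental ones (2.72-fold and 2.48-fold by parental replicate 2 alone). Of the 10 circRNAs named on the higher side, 8 were also higher in resistant HCC827 cells, 3 of them at least 2-fold, and hsa_circ_0075641 was lower there by at least 2-fold. Of the 10 on the lower side, 3 were near background on both HCC827 arrays, and 6 were also lower in resistant HCC827 cells, 5 of them at least 2-fold with values below background raised to it. By the values as deposited, 51.1% of all features kept had the same sign in both lines. So did 1302 of the 2606 changed at least 2-fold at an unadjusted p under 0.05 (limma) in H1975. As circRNAs with neighbouring numbers changed together, the counts among the named ones are not counts of separate cases. The unnamed LNCV6 probes with the smallest p were LNCV6_144708_PI430048170 (at least 20.8-fold, with both parental signals near background) and LNCV6_138075_PI430048170 (log2 difference 4.75) on the higher side, and LNCV6_89595_PI430048170 and LNCV6_142112_PI430048170 on the lower side (-3.49 and -3.58, the latter with 1 of 2 resistant signals near background).

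With limma, 0 of 131735 features passed an adjusted p of 0.05 between resistant and parental H1975 cells. At an unadjusted p under 0.05 there were 2612 (1864 higher and 748 lower in resistant cells), where 6587 would be expected by chance. Since arrays with one number deviated together, the same comparison was made within pairs, and then 966 features passed (647 higher and 319 lower; 401 circRNAs and 565 LNCV6 probes), among them all 20 circRNAs named above, at adjusted p up to 0.0268, which had been picked for small p on the same arrays. At an unadjusted p under 0.05 there were 8806 within pairs, where again 6587 would be expected by chance. The 4 LNCV6 probes named above, likewise picked for small p, also passed within pairs, at adjusted p (limma) up to 1.11e-05. The test within pairs has 1 residual degree of freedom and borrows nearly all of its spread from other features. Its median SE was 0.558, against 0.561 without pairs, while its prior degrees of freedom were 172 against 3.6. Of its 966 features, 507 differed at least 2-fold the same way in both pairs, and 202 differed in opposite directions in the 2 pairs.

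Across features the changes in the 2 H1975 pairs had a linear correlation near 0 (r = 0.00455). In pair 1, 13829 features were at least 2-fold higher and 14496 at least 2-fold lower in resistant cells. In pair 2 the numbers were 17341 and 12726. Among the 8349 features that differed at least 2-fold in both pairs, 2951 were higher in both, 1443 were lower in both and 3955 went in opposite directions. If the pairs were independent, 1820 would be higher in both, 1400 lower in both and 3244 opposite, so both the same and the opposite direction exceeded independence. The circRNA probes of pair 2 leaned upwards, with 11086 at least 2-fold higher and 4987 lower, while its LNCV6 probes leaned downwards, with 6255 higher and 7739 lower (median log2 differences 0.08 and -0.21). As each array was given the same distribution, these leans cannot be read independently. The circRNA probes of pair 1 were balanced at 8379 and 8190. In pair 2 the E1A and DCP control probes were also lower in the resistant sample, by a median of -0.89 on the log2 scale.

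**Figure D2:**
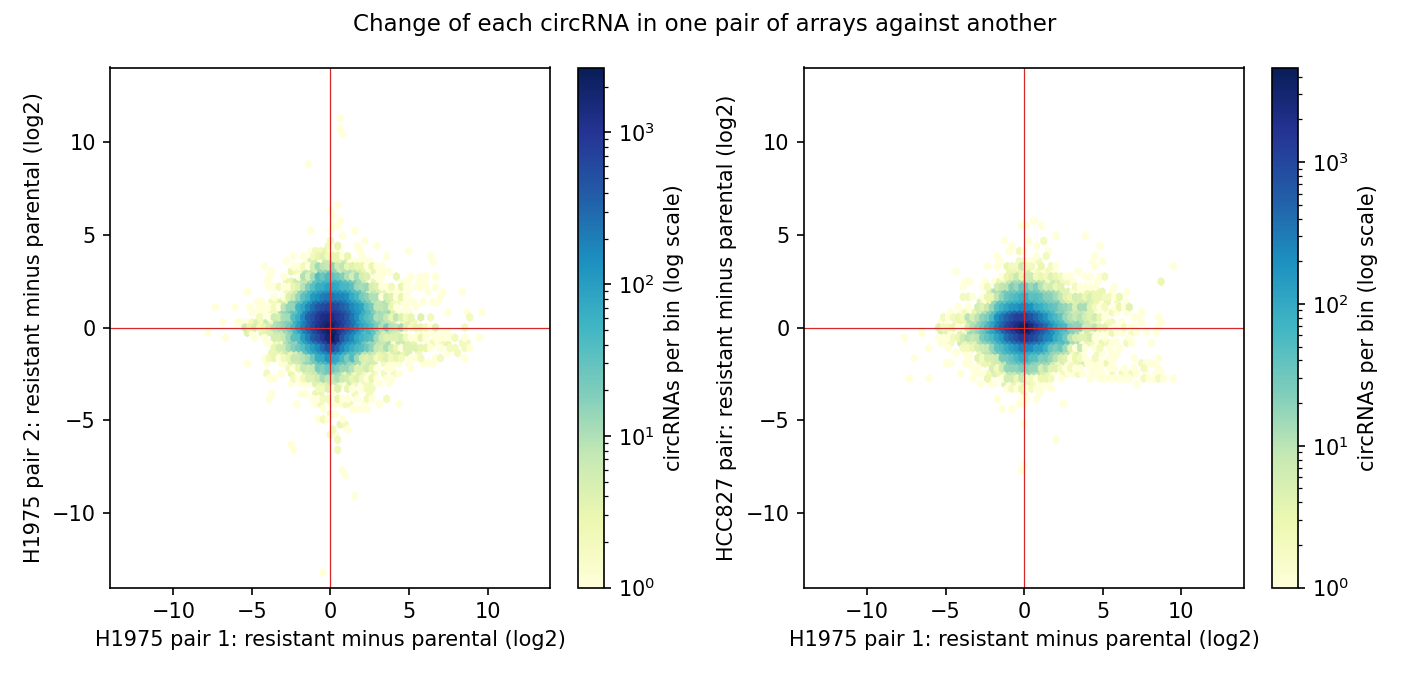
Resistant minus parental log2 signal of each of the 80365 circRNAs kept, with H1975 pair 1 on the horizontal axis and H1975 pair 2 (left) or the HCC827 pair (right) on the vertical axis; colour gives circRNAs per bin on a log scale. Neither cloud follows a diagonal, with r across circRNAs of 0.00228 on the left and -0.0349 on the right.

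The 16 circRNAs chosen before the data were examined, for known roles or earlier study in lung cancer, were all on the array, and 3 were higher in resistant cells in all 3 pairs, 1 was lower in all 3 and 12 were mixed. In H1975 0 passed limma's test over all features or adjusted over the list alone, where the lowest adjusted p was 0.701, and 0 had an unadjusted p under 0.05. The changes were opposite in the 2 H1975 pairs for 9 of the 16. CDR1as (hsa_circ_0001946), a circRNA that binds the microRNA miR-7, went from 3.03 in parental to 7.90 in resistant cells in pair 1, from 3.08 to 1.89, near background, in pair 2 and from 4.06 to 2.96 in HCC827. The circRNA hsa_circ_0002130, of the complement gene C3 and studied in osimertinib resistance, went from 0.78, near background, to 9.58 in pair 1, but from 7.46 to 6.23 in pair 2 and from 8.22 to 5.51 in HCC827. Its comparison within pairs gave an adjusted p of 5.53e-05 (limma) at a mean log2 difference of 3.79, although it was higher in resistant cells in only 1 of the 3 pairs.

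Of the listed circRNAs, hsa_circ_0004015, from the kinase gene CDK14, was higher in resistant cells in all 3 pairs, by 2.37, 0.83 and 1.02 on the log2 scale. The H1975 difference was 1.60 (SE 0.68) and did not pass the test. The other members higher in all 3 were circCCDC66 (hsa_circ_0001313; 0.82, 0.05 and 0.25) and hsa_circ_0014130 (0.39, 0.50 and 0.04), and circPVT1 (hsa_circ_0001821), from the PVT1 locus beside MYC, was lower in all 3 (-1.35, -0.85 and -0.34). The circPVT1 signal was 10.47 and 9.12 on the H1975 replicate 1 arrays and between 4.69 and 5.59 on the other 4, so its difference between replicates exceeded that between resistant and parental cells. CircHIPK3 (hsa_circ_0000284) had a difference of 0.07 (SE 0.61) in H1975 and signals from 6.44 to 7.74 on all 6 arrays. Leaving out 1 H1975 array turned the sign of the H1975 difference for 8 of the 16, among them CDR1as (-1.17 without resistant replicate 1, which rests on the resistant signal near background) and circPVT1 (1.36 without parental replicate 1 and 1.11 without resistant replicate 2).

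**Figure D3:**
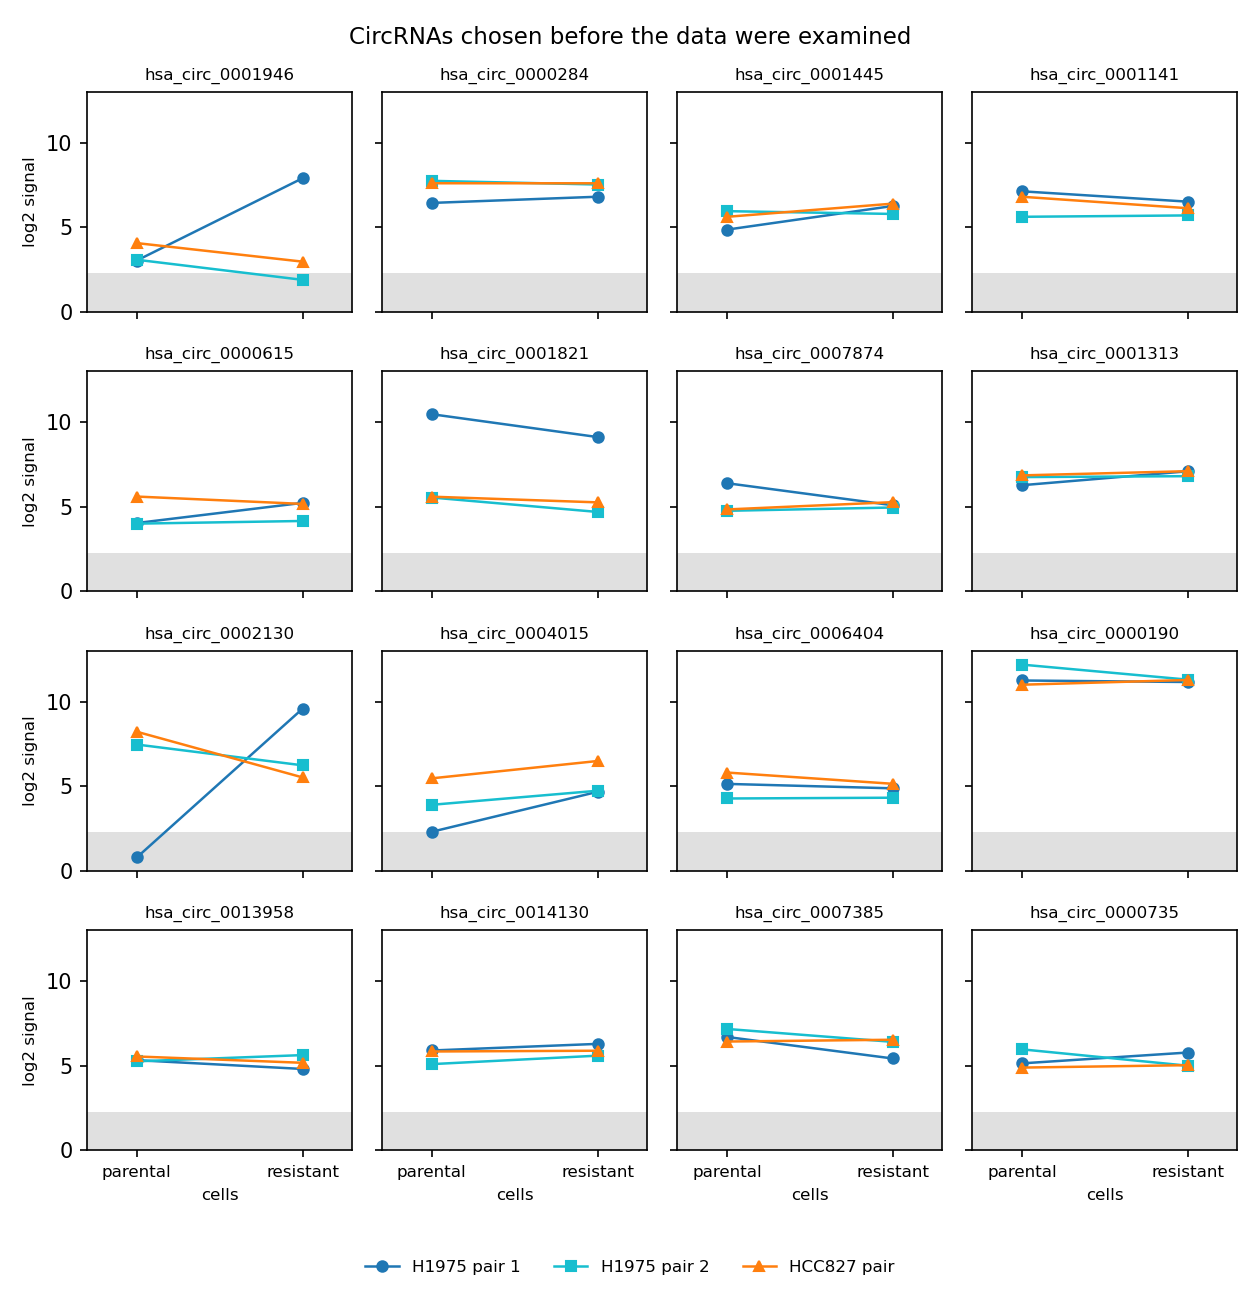
Log2 signal of the 16 circRNAs chosen before the data were examined, in parental and resistant cells; each point is 1 array, lines join the arrays of a pair, and the grey band lies below the highest background level (2.28). Lines of different pairs cross for hsa_circ_0002130 (0.78 to 9.58 in H1975 pair 1, 8.22 to 5.51 in HCC827), while the circPVT1 probe hsa_circ_0001821 is higher in H1975 pair 1 than on the other arrays.

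The change shared by both lines was estimated from all 6 arrays with the cell line as a term. The circRNA hsa_circ_0043610 was higher in resistant cells by 4.88 in H1975 pair 1, 4.20 in H1975 pair 2 and 4.30 in HCC827 (3.58 to 7.88, 19.7-fold), a mean log2 difference of 4.46 (SE 0.45). It was at least 3.69 with values below background raised to it, since both parental H1975 signals were near background. Its neighbour in number, hsa_circ_0043611, and hsa_circ_0013368 were near background on all 3 parental arrays. The former was at least 3.29-fold higher in resistant H1975 and 14.8-fold higher in resistant HCC827 cells, and the latter at least 1.94-fold and 4.22-fold. The H1975 bound of hsa_circ_0043611 rests more on replicate 1, with a resistant signal of 4.75 against 3.16 in replicate 2. Also higher in all 3 resistant arrays were hsa_circ_0004190 (2.75, SE 0.43) and hsa_circ_0005480 (3.02, SE 0.58), each near background on 1 of the 3 parental arrays. Lower in all 3 were hsa_circ_0060328 (-2.68, SE 0.36) and hsa_circ_0019975 (-2.74, SE 0.42), each near background on 1 of the 3 resistant arrays, and hsa_circ_0083082 (-1.97, SE 0.38), hsa_circ_0083084 (-2.09, SE 0.44) and hsa_circ_0016236 (-1.80, SE 0.35).

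With limma 0 of the 131735 features passed over both lines, and 2739 had an unadjusted p under 0.05 (1765 higher and 974 lower). Within pairs 0 passed as well, with 5848 at an unadjusted p under 0.05, and the smallest adjusted p, 0.0621, was that of hsa_circ_0043610. Without the 2 arrays of H1975 pair 1, a choice made after seeing the data, 184 features passed (88 higher and 96 lower) in a fit with 1 residual degree of freedom. Without H1975 pair 2 or without HCC827, 0 passed.

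**Figure D4:**
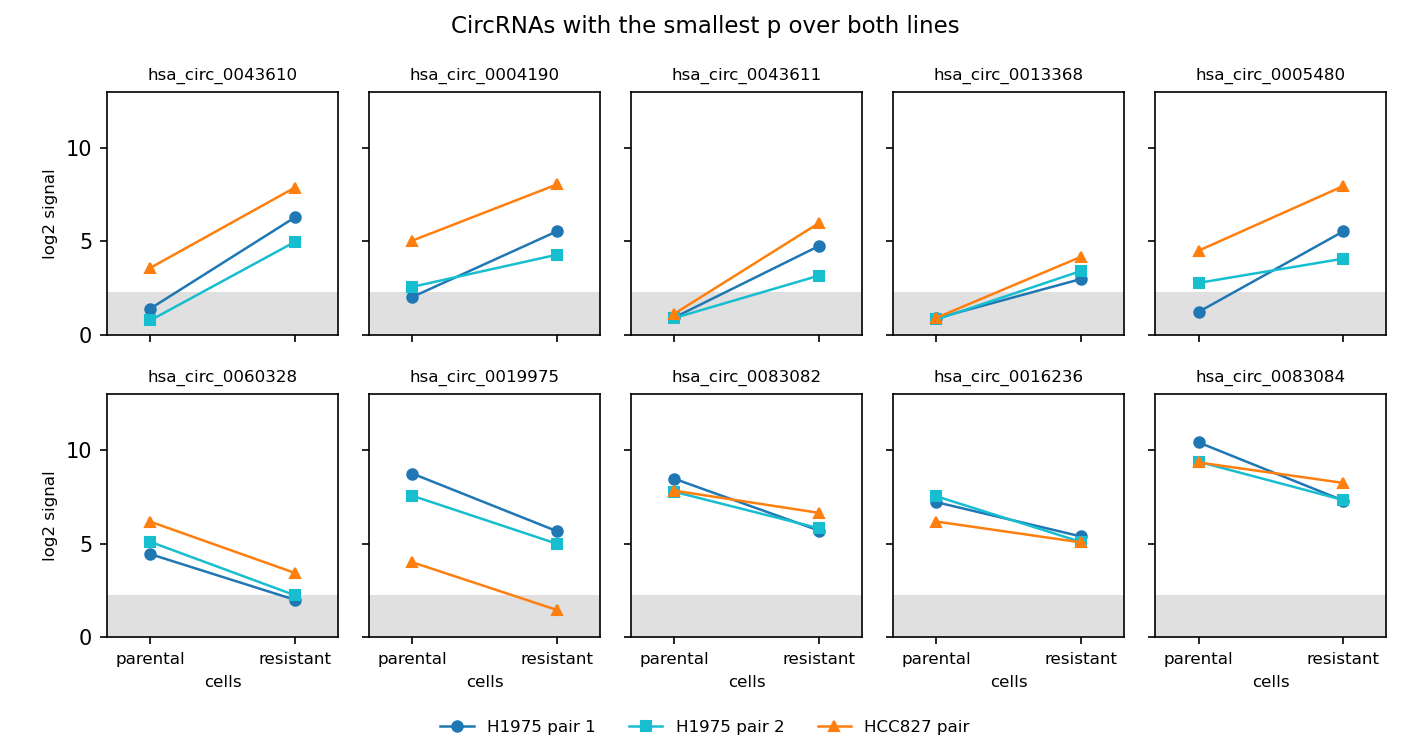
Log2 signal of the 10 circRNAs with the smallest p over both lines, in parental and resistant cells; each point is 1 array, lines join the arrays of a pair, and the grey band lies below the highest background level (2.28). All 3 lines slope the same way in each panel because the circRNAs were picked for it, as in hsa_circ_0043610 (4.88, 4.20 and 4.30 on the log2 scale).

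In HCC827, with 1 array per group, differences have no replicate check. Resistant and parental cells differed at least 2-fold in 15122 features (7992 higher and 7130 lower), or 11.5%, against 21.5% and 22.8% within the H1975 pairs. Replicates of the same H1975 group differed in 31.6% and 27.0%. Those shares lie across pairs and include the offset of the H1975 replicate 1 arrays, so they do not measure the spread within HCC827. Among brighter circRNAs, hsa_circ_0053903 went from a log2 signal of 2.49 in parental to 8.31 in resistant HCC827 cells, while in H1975 it was 3.36 ± 0.97 in parental and 3.65 ± 0.71 in resistant cells. The circRNA hsa_circ_0002474 went the other way, from 8.92 to 3.02 (59.6-fold lower). The other named differences were 3.81 (hsa_circ_0051417), 3.46 (hsa_circ_0005480) and 3.28 (hsa_circ_0028004) on the higher side. On the lower side they were -3.95 (hsa_circ_0071559), -3.36 (hsa_circ_0054649), -3.25 (hsa_circ_0007362) and -3.10 (hsa_circ_0048885). Of these, hsa_circ_0071559 ranged only from 4.26 to 4.54 over the 4 H1975 arrays, and hsa_circ_0007362 was also lower in H1975 pair 2 (9.07 to 5.06) but not in pair 1 (8.98 to 9.89).

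The responses of the lines were then set against each other. The difference of response was largest among the circRNAs named for HCC827 at hsa_circ_0002474 (-7.48, SE 2.06) and hsa_circ_0048885 (-6.18, SE 3.08), with an adjusted p of 1 for both. Both H1975 pair 2 signals of the former were near background. The latter changed by 7.09 in H1975 pair 1, from a parental signal near background, but by -0.92 in pair 2, the direction seen in HCC827, so its difference of response rests on pair 1. With limma 0 features passed the test of the difference, and 1193 had an unadjusted p under 0.05. The comparison within pairs gave 223 (93 with the larger value in HCC827 and 130 with the smaller). This test assumes that the single HCC827 arrays vary like the H1975 ones. Across features the H1975 and HCC827 changes had an r of 0.0351. Of the 2606 features at least 2-fold changed at an unadjusted p under 0.05 in H1975, 1302 had the same sign in HCC827, while the same-sign share over all features was 51.1%. At least 2-fold in HCC827, 11.7% of the 2606 went the same way and 6.68% the opposite way, where independence would give 5.88% and 5.60%. With values below background raised to it, a choice made after seeing the data, these were 8.63% and 5.22% against 3.87% and 3.73%. No test was made of this excess.

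Between the cell lines at equal resistance status 24 features were called, all 24 higher in HCC827, of which 2 were circRNAs and 22 LNCV6 probes. The fit counts the arrays of a pair as independent, although HCC827 is a single pair. With H1975 pair 1 set against the other 4 arrays instead, a test chosen after seeing the data, 2769 features were called, and with H1975 pair 2 there were 80. The 24 therefore do not exceed the number called for a pair of one line. The circRNAs have consecutive numbers. The signal of hsa_circ_0025367 was 8.28 and 9.05 in HCC827 and between 0.86 and 1.65, near background, on all 4 H1975 arrays, a log2 difference of 7.58 (SE 0.42, limma adjusted p = 0.0137), and of at least 6.49 with the H1975 values raised to the background level. That of hsa_circ_0025368 was 9.12 and 9.87 in HCC827 and between 1.03 and 2.54 in H1975 (difference 8.01, SE 0.54, limma adjusted p = 0.0201), where 3 of the 4 arrays were near background and the difference was 7.25 with values raised to that level. Neither circRNA passed without the filter on dim features (adjusted p = 0.126 for both, limma), where 0 features were called in all. At an unadjusted p under 0.05 there were 9980 features (5159 higher in HCC827). The number of calls rested on single arrays, with 0 without parental H1975 replicate 1, without parental H1975 replicate 2 or without either HCC827 array, and 14 without resistant H1975 replicate 2. It was 5670 without the 2 arrays of H1975 pair 1, 1732 without those of pair 2 and 4643 with the replicate number as a block. Each of these 3 fits sets the HCC827 pair against 1 H1975 pair, the last 2 against the same one, so none adds a replicate of either line.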

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

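The tests on companion probes, control probes, replicate numbers, features near background in 1 pair, dim features and signal-dependent shifts were chosen after the patterns had been seen; the counts over other splits of the arrays were planned.

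Companion probes, which no comparison in the report uses, carried changes related to those of the circRNA probes they are named after, though not always in the same direction. Over 98 circRNAs with 372 such probes, resistant minus parental differences of the array probe and the median of its companions correlated at r = 0.865 in H1975 pair 1. In 1000 shuffles r was at most 0.282. The correlations were 0.736 in H1975 pair 2 and 0.619 in HCC827. The array probe and its companions changed with the same sign for 82.7% of the circRNAs in H1975 pair 1, 74.5% in H1975 pair 2 and 71.4% in HCC827. Between pairs the companion changes correlated at -0.00525 for the H1975 pairs, -0.104 for H1975 pair 1 with HCC827 and 0.122 for H1975 pair 2 with HCC827. Over all circRNA probes kept the values were 0.00228, -0.0349 and 0.0494.

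Control probes of the E1A and DCP series, also outside the comparisons, differed in H1975 pair 2, where the median of resistant minus parental was -0.89 over 28 probes and 27 of them were lower in the resistant sample. In H1975 pair 1 the median was 0.11 and in HCC827 it was -0.07.

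The H1975 replicate 1 arrays stood apart from the other 4. Noise of single probes is argued against, since differences between replicates of array and companion probes correlated at 0.879 in both groups. A batch shared by all arrays numbered 1 is argued against as well, because the HCC827 arrays, also numbered 1, correlated better with H1975 replicate 2, by 0.027 on average. A batch holding the H1975 replicate 1 arrays alone would set them apart in the same way. It was not tested, as the labels name no batch. A different culture or line behind one H1975 pair cannot be told apart from drift within H1975: HCC827 was closer to H1975 replicate 2 than the H1975 pairs were to each other, by 0.0355, but no gene known to separate the lines is named on the array. Against HCC827 cells behind H1975 replicate 2 stands hsa_circ_0025367, at 8.28 and 9.05 in HCC827 and near background on all 4 H1975 arrays, but it was picked by that comparison. In all, 64 features were above 5 on both HCC827 arrays and near background on both H1975 replicate 2 arrays, and 63 the other way round. Between the H1975 pairs there were 276 and 200, so such features do not decide it. No biological explanation was tested, since the design gives none for a difference between replicates.

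The responses of the 2 H1975 pairs had a linear correlation near 0 (r = 0.00455), though more features changed at least 2-fold in both pairs than independence gives, the same way (2951 higher in both against 1820) and opposite ways (3955 against 3244). Probe noise is argued against by the companion probes (0.736 or higher within each pair). Dilution by dim features is argued against, since r was -0.0629 over the brightest 20% of features. After a lowess curve on mean signal was removed r was 0.00505, but the curve held at most 0.0361% of the variance of the differences, so its removal tested nothing. The size of the curve itself argues against a smooth shift with mean signal. It ran from -0.0593 to 0.00456 in H1975 pair 1 and from -0.0497 to 0.0438 in pair 2, where the differences had SDs of 0.981 and 0.93. A hypothesis that stays open and untested is that the resistant cells behind each array pair differ from their parental cells in different ways, which may reflect separate selections or separate cultures.

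For the shared change over both lines, 10 splits of the 6 arrays into 3 against 3 exist, too few for a share under 0.05. The real split had 2739 features at an unadjusted p under 0.05, 8 of the 10 splits had at least as many, and the highest other had 12679. It had 0 calls, which all 10 splits reach, and the highest other had 99. The latter split set resistant H1975 replicate 1 and both HCC827 arrays against the rest. The split with the most features at an unadjusted p under 0.05 had parental H1975 replicate 2 and both HCC827 arrays on one side. With the cell line as a term, HCC827 arrays on one side add nothing to the estimated difference. Each of these splits therefore set 1 H1975 array against the other H1975 arrays, and neither follows resistance. The real split keeps the members of all 3 pairs apart, as do 3 others, with 1968 to 3300 features.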

How the results depend on the processing

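The settings with a pair left out, values raised to background and a lowess curve removed were chosen after seeing the data. With the replicate block, 966 features passed in H1975, 223 for the difference of response and 4643 for the cell lines, the last taken from the replicate 1 arrays alone. The block changed no other count of calls. In H1975 the median SE was 0.561 without and 0.558 with the block, while the prior degrees of freedom went from 3.6 to 172. For the difference of response the median SE was 0.969 and 0.972, and the prior degrees of freedom 3.64 and 1010. Calls in both thus came with a change of the variance prior, not with a smaller median SE. For the cell lines the cause was not tested. The unadjusted threshold with 2-fold gave 2606 (H1975), 2052 (both lines), 1193 (difference of response) and 8269 (cell lines), as a looser criterion must. Leaving out H1975 pair 1 gave 184 over both lines and 5670 between cell lines, and leaving out pair 2 gave 1732 between cell lines. The 24 cell line calls went to 0 without a filter, to 7 in the upper signal range and to 0 to 16 without single arrays, where fewer arrays were tested. HCC827 features past 2-fold went from 15122 to 4216 in the upper signal range, 2438 at 4-fold and 10019 with values raised to background, so many lay near background. All other settings run kept the counts of 0 for resistance. Of the named circRNAs and LNCV6 probes, 708 values under alternatives kept direction and side of the threshold, 31 passed it newly (with the block or without H1975 pair 1), 12 no longer passed (the cell line circRNAs, without a filter or without 1 array) and 13 reversed. All 13 were H1975 differences of listed circRNAs with 1 array left out, ranging from -1.17 to 4.85 (hsa_circ_0001946), -0.58 to 0.73 (hsa_circ_0000284), -1.02 to 0.49 (hsa_circ_0001141), -3.57 to 1.36 (hsa_circ_0001821), -1.37 to 0.26 (hsa_circ_0007874), -0.54 to 0.32 (hsa_circ_0006404), -0.48 to 0.34 (hsa_circ_0013958) and -0.58 to 0.25 (hsa_circ_0000735). Gene list and host gene alternatives were not run, for want of gene names. Signal near background limits folds to lower bounds for 9 of the 20 circRNAs named in H1975.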

Other observations

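The tests on runs, neighbouring numbers, single-array signals and exchanged labels were chosen after the data had been seen.

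Several stretches of consecutive circBase numbers changed in opposite directions in H1975 pair 1 and in the other 2 pairs. CircRNAs numbered hsa_circ_0048889 to hsa_circ_0048891 had mean log2 differences between resistant and parental cells of 6.55 in H1975 pair 1, -1.12 in H1975 pair 2 and -2.39 in HCC827, and hsa_circ_0048853 to hsa_circ_0048855 of 7.85, -1.23 and -2.65. The values for hsa_circ_0017874 to hsa_circ_0017876 were 2.59, -2.42 and -1.80. A long stretch went the other way, with -1.21, 1.08 and 1.32 for hsa_circ_0068595 to hsa_circ_0068597 and -1.28, 1.22 and 1.19 for hsa_circ_0068629 to hsa_circ_0068631. In all, 27 runs of 3 consecutive numbers, covering 53 circRNAs, changed at least 2-fold in this opposed way, 12 of them higher in pair 1 and 15 lower. These means were not bounded for signal near background. The circRNA hsa_circ_0048885, numbered between the first runs given here, was near background on parental H1975 replicate 1 (1.46), so such means may not be exact.

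Runs of 3 that changed at least 2-fold the same way in all 3 pairs numbered 13 of the 65877 searched. Mean log2 differences in H1975 pair 1, H1975 pair 2 and HCC827 were 4.06, 2.82 and 3.79 for hsa_circ_0043609 to hsa_circ_0043611, and 2.26, 2.30 and 2.30 for hsa_circ_0054973 to hsa_circ_0054975. They were 5.14, 2.71 and 1.32 for hsa_circ_0077059 to hsa_circ_0077061 and -2.91, -1.81 and -1.12 for hsa_circ_0083082 to hsa_circ_0083084. These include hsa_circ_0043610, hsa_circ_0043611 and hsa_circ_0077059, whose parental H1975 signals were near background, so the means of their runs are not exact. Turning the sign of pair 2 alone gave 3 runs and turning that of HCC827 alone gave 0. Runs overlap along stretches of numbers, and many of the 27 opposed ones lie between hsa_circ_0068595 and hsa_circ_0068631. The counts of 27 and 13 are therefore not counts of separate events and cannot be ranked. As opposed runs occur too, the 13 do not by themselves show a response shared by the 3 pairs.

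CircRNAs with consecutive numbers changed together in each pair. Over 72356 such neighbours, resistant minus parental differences correlated at 0.6 in H1975 pair 1, 0.357 in H1975 pair 2 and 0.335 in HCC827, against at most 0.0102 for random partners, which argues against noise of single probes. The explanations that stay open are untested, as the files give neither gene names nor probe sequences. Neighbours may be circles of one gene that follow its transcription, or their probes may share sequence and catch the same RNA.

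Some features were bright on 1 array and near background on the other 5. The circRNA hsa_circ_0087840 reached a log2 signal of 14.08 on the parental H1975 replicate 2 array and at most 1.68 elsewhere, and hsa_circ_0007673 reached 12.09 on the resistant H1975 replicate 2 array and at most 1.26 elsewhere. The opposite, near background on 1 array and above 5 on every other, was seen for 65 features on parental H1975 replicate 1, 45 on resistant H1975 replicate 1, 9 on resistant H1975 replicate 2 and at most 2 on any other array.

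Exchanging resistant and parental labels in H1975 pair 2 left 0 features called within pairs, against 966 with the labels as given, while 7207 and 8806 had an unadjusted p under 0.05. The 2 counts do not stand on one footing, since the prior degrees of freedom were 11.6 and 172. Of the 966, 198 changed in the same direction in both H1975 pairs and at least 2-fold that way in HCC827. The 202 with opposite directions in the H1975 pairs could not enter that count. Over all features kept, 11.5% differed at least 2-fold in HCC827 in either direction. In 422 of the 966 an H1975 pair was under 2-fold.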
